A study of Mus musculus with 12 samples.

How the data were processed

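MeCP2, a protein that binds methylated DNA and is mutated in Rett syndrome, was measured on chromatin by immunoprecipitation followed by sequencing (ChIP-seq). The tissue was forebrain, meaning cortex and hippocampus together, of male C57BL/6 mice aged 8 to 11 weeks. Wild-type (WT) mice were compared with mice of an Mecp2 knock-in line that the labels call QKI and the column names of the table call Quad. Both names were taken to mean the same mice, since the groups and replicate numbers match. Each genotype had 3 ChIP libraries and 3 input libraries, in which fragmented chromatin was sequenced without immunoprecipitation. The labels do not say that each replicate number is a separate animal, so the p-values measure the spread between these libraries.

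The deposited table holds raw counts, whole-number reads per gene-body interval, with no scaling applied by the authors. Per the submitters' processing notes, Trimmomatic 0.36, Bowtie2 2.2.9, SAMtools 0.1.19 and bedtools were used with the mm10 build of the mouse genome. The role and order of these tools, the treatment of reads that align to several places, and any removal of duplicates or subsampling are not given in the sources used here. Of the 17929 intervals, 17282 (96.4%) carried a symbol found among RefSeq genes of the same build. Of 17267 matches on the same chromosome, 8513 intervals start exactly 3 kb inside the 5′ end of the RefSeq gene, and the median gap was 3000 bp. No interval is shorter than 1500 bp. The median interval measured 20305 bp and the longest 2267659 bp. Promoter reads lie outside those 8513 intervals, and for the others this was not settled. In total 1981 intervals (11.0%) overlapped another interval, so a read can be counted for more than 1 gene. Genes named in the report whose intervals overlap another are given as such and are uncertain, as are the clustered protocadherins as a group. Which genes belong to repeated families was not settled, so counts of receptor, pseudogene and predicted genes are uncertain too. No genome sequence was used here, so the dependence of the counts on base composition or repeated sequence was not examined.

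Library totals ran from 9445491 to 10367419 gene-body reads, and the median count per interval ran from 167 to 190. Counts were analysed in edgeR 4.0.16 with R 4.3.3. The default expression filter, with its minimum count of 10, removed 14 intervals and left 17915. Library sizes were scaled by trimmed mean of M-values (TMM), with factors from 0.967 to 1.03. The common biological coefficient of variation was 3.83%. A single quasi-likelihood model was fitted to all 12 libraries with 1 mean per group, and 5 differences were tested with it. These were WT ChIP over WT input, QKI ChIP over QKI input, the difference between those 2 ratios, QKI against WT ChIP, and QKI against WT input. The p-values were adjusted by the Benjamini-Hochberg method over all genes tested, and an adjusted p under 0.05 counted as passing. Errors beside log2 changes are standard errors of the model, with 3 libraries per group.

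A set of 33 gene lists was tested with camera in limma 3.58.1 on voom-transformed counts, using a preset correlation between genes of 0.01, and adjusted over the lists within each comparison. The histone list had 2 members and the keratin-associated protein list had 0, so 31 lists were tested. List sizes count only members with a tested interval, such as 13 immediate early genes and 11 housekeeping genes, and are not family totals. Why other members had none was not examined, but no interval is shorter than 1500 bp, so short genes may be missing. Beside the preset, camera was run with a correlation estimated from the data, and fry was run. None of the list calls held with an estimated correlation in any of the 5 comparisons. Fry asks whether the genes of a list move on balance in 1 direction, without comparing them with other genes. Under fry, 14 lists passed in WT, 16 in QKI and 0 in each of the 3 genotype comparisons. List counts are given over all genes tested and adjusted over the list alone.

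Genes were named by a rule. It took genes with a mean count of at least 100, an adjusted p under 0.05 and all 3 libraries of one group beyond all 3 of the other, and of these the 10 largest rises and the 10 largest falls. Where fewer than 5 genes met it, the 5 smallest p-values in each direction were taken as values that did not pass. A fixed set of genes, and the 4 members with the smallest p of each list that passed, were added. Of that fixed set, Fos, Arc, Sst and Actb were not analysed here, since the table used holds no interval under their symbols.

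Whether replicate numbers pair ChIP with input was checked from the deviations of each library from its group mean across genes. In QKI, same-numbered ChIP and input libraries correlated at 0.555, 0.195 and 0.350, all over the limit of 0.1 set for pairing. Libraries of different numbers passed it too, at 0.212 for ChIP 3 with input 2 and 0.185 for ChIP 2 with input 3. So the numbers clearly pair only QKI replicate 1, and replicates 2 and 3 are not told apart. A fit with the pair as a block called 8750 genes in QKI against 7430 without it. The pairing comes from the data and not from the labels. QKI replicate 1 stood apart from the other libraries. Pairs of libraries of 1 group differed by a chi-square of 1.09 to 1.67 per degree of freedom, except the pairs that held QKI replicate 1, which reached 2.58 to 3.25. Its residual spread across genes was 0.11 on the log2 scale in ChIP and in input.

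The procedure was tested on simulated data with no difference except in 200 genes. It recovered 80% of genes changed 1.5-fold in WT, 75% in QKI, 59% in the difference between ratios, 76% in ChIP and 68% in input. For 2-fold changes it recovered 95%, 95%, 84%, 93% and 91%. The share of calls that were false lay between 4.52% and 12.6% in single draws, and it was 6.71% over 12 further draws of the comparison with the highest share. A list raised 1.1-fold passed with camera at an adjusted p of 4.28e-36, and 0 of the other lists passed. The simulated counts were drawn independently for each gene and library. They held no correlation between genes, no pairing of ChIP with input and no outlying replicate. So they do not show that these rates, or the list test, hold for the real libraries. Alternatives covered scaling with DESeq2 1.42.0 size factors or library size, other filters, the DESeq2 and limma-voom tests, fewer libraries per fit, replicate blocks, offsets that follow abundance, and each library left out in turn. Chosen after the data had been seen were offsets that follow input reads per kb, a fit without both QKI replicate 1 libraries, the block within genotype with an estimated correlation, and a count of the clustered protocadherin genes on stretches that belong to 1 interval each.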

Results

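MeCP2 ChIP-seq and input reads were counted over gene bodies in forebrain of WT mice and of mice of the QKI knock-in line. The series concerns phosphorylation of MeCP2 that neuronal activity induces, and the refinement of synapses between retina and thalamus. There were 3 ChIP and 3 input libraries per genotype. WT ChIP libraries held 9445491 to 9581207 counted reads and WT inputs 9615672 to 9727756. QKI ChIP libraries held 9559012 to 10001657 and QKI inputs 9832205 to 10367419. The standard error of a ChIP-over-input change had a median of 0.10 on the log2 scale in each genotype, and 0.07 among the 11923 genes with a mean count of at least 100. All ChIP values below are relative to input or to the other genotype after scaling, so none gives the absolute amount of MeCP2.

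The first comparison asked where MeCP2 lay over gene bodies in WT forebrain relative to input. Under the naming rule, which asks for a mean count of at least 100, the largest rise was on Dhrsx, by 1.13 ± 0.15 on the log2 scale (adjusted p = 7.51e-06), on a scaffold assigned to chromosome 4 without a position. Bmi1, a Polycomb group gene (mm10, chromosome 2, start 18680018, end 18686629), rose by 1.04 ± 0.13 (adjusted p = 3.51e-06). Further rises were on Pus7l (0.82 ± 0.10), the growth factor gene Fgf5 (0.79 ± 0.09), the galanin receptor gene Galr1 (0.77 ± 0.12), 4930567J20Rik (0.76 ± 0.09) and the Wnt ligand gene Wnt16 (0.76 ± 0.12). The casein gene Csn1s2a (0.73 ± 0.12), the germ-cell gene Dazl (0.73 ± 0.08) and the pituitary transcription factor gene Pou1f1 (0.72 ± 0.10) completed the 10 largest that the rule took. On the other side, Vax2os lay below input at -0.86 ± 0.12, Safb2 at -0.80 ± 0.10, the homeobox gene Pitx2 at -0.76 ± 0.12, the kinase gene Clk3 at -0.75 ± 0.12 and A330023F24Rik at -0.75 ± 0.10. The tumour suppressor gene Cdkn2a (-0.75 ± 0.13), the spinophilin gene Ppp1r9b (-0.75 ± 0.14) and Tagln3 (-0.73 ± 0.13) also fell. Hoxa3 (-0.78 ± 0.09) and the thyroid hormone receptor gene Thra (-0.77 ± 0.09) fell as well, with intervals that overlap those of other genes.

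In all, 5992 of 17915 genes (33.4%) passed in WT by the edgeR quasi-likelihood test, 2961 above input and 3031 below. Of these, 411 differed by more than 1.5-fold and 34 by more than 2-fold. Scaling by library size alone called 6014 genes but only 1927 above input against 4087 below, because it moved the median of all genes from -0.01 to -0.06. Among the genes fixed for naming, Mecp2 itself lay at -0.69 ± 0.07 (chromosome X, start 74026592, end 74082690; adjusted p = 1.86e-07). Counts over the Mecp2 gene measure neither the protein nor the knock-in. The autism-linked gene Auts2 rose by 0.31 ± 0.04 (adjusted p = 1.59e-06), and Bdnf, a neurotrophin gene that activity induces, rose by 0.20 ± 0.06 (adjusted p = 0.00922). Without WT input replicate 1, the adjusted p of Bdnf was 0.0669. The synaptic adhesion gene Nrxn1, whose interval overlaps another, lay at -0.06 ± 0.05 (adjusted p = 0.334). It passed in opposite directions with other offsets, at 0.10 with those that follow read density (adjusted p = 0.0121) and at -0.23 with those that follow abundance and a replicate block (adjusted p = 2.32e-05). Npas4 (-0.18 ± 0.27) and Gapdh (-0.32 ± 0.29) did not pass and had mean counts of only 22.0 and 14.2.

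Several groups of genes lay below input in WT. Of 21 genes of MeCP2 and its partners, 11 fell and 1 rose, with the same counts when adjusted over the list alone (camera adjusted p = 0.000101, but adjusted p = 0.345 with an estimated correlation). Among them were the DNA methyltransferase gene Dnmt3a (-0.47 ± 0.05), the corepressor gene Ncor2 (-0.38 ± 0.05; 5, start 125017153, end 125176214) and the chromatin remodeller gene Atrx (-0.41 ± 0.06), while Dnmt3b was the member that rose (0.24). Of 13 Hox genes, 9 fell and 0 rose, and so did 9 adjusted over the list alone (camera adjusted p = 2.16e-05, adjusted p = 0.176 with an estimated correlation). Examples were Hoxd3 (-0.60 ± 0.08), Hoxb5os (-1.08 ± 0.15) and Hoxa10 (-1.23 ± 0.25), of which Hoxd3 overlaps another interval. Of 352 zinc finger genes, 113 fell and 17 rose, or 120 and 19 adjusted over the list alone (camera adjusted p = 1.18e-05, adjusted p = 0.176 with an estimated correlation). Zfp638 fell (-0.35 ± 0.06), but the 3 members with the smallest p rose, namely Zfp521 (0.52 ± 0.05), Zfp407 (0.46 ± 0.04) and Zfp423 (0.30 ± 0.04). Of 24 genes near Mecp2 on the X, 9 fell and 0 rose, with 9 adjusted over the list alone, such as Hcfc1 (-0.76 ± 0.13), L1cam (-0.63 ± 0.14) and Ikbkg (-0.29 ± 0.08, overlapping). The camera adjusted p of that list was 0.000215, with an adjusted p = 0.199 with an estimated correlation.

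The complex I and housekeeping lists lay below input too. Of 35 complex I genes, which build the first complex of the respiratory chain, 14 fell and 1 rose, or 15 and 1 adjusted over the list alone (camera adjusted p = 0.00205, adjusted p = 0.345 with an estimated correlation). The riser was the assembly factor gene Ndufaf2 (0.20 ± 0.04), while Ndufv2 (-0.36 ± 0.08), Ndufaf1 (-0.66 ± 0.17) and Ndufs7 (-0.70 ± 0.18) fell. Of 11 housekeeping genes, 6 fell and 0 rose, or 8 and 1 adjusted over the list alone (camera adjusted p = 0.00737, adjusted p = 0.341 with an estimated correlation). Examples were the transferrin receptor gene Tfrc (-0.51 ± 0.08), Ywhaz (-0.40 ± 0.08), Sdha (-0.42 ± 0.09) and Pgk1 (-0.67 ± 0.15). Of 39 clustered protocadherin genes, 36 fell and 0 rose, with 36 adjusted over the list alone (camera adjusted p = 1.61e-15, adjusted p = 0.235 with an estimated correlation). Pcdhgc4 (-0.54 ± 0.09), Pcdhgc5 (-0.53 ± 0.09), Pcdhga7 (-0.31 ± 0.05) and Pcdhga6 (-0.30 ± 0.05) had the smallest p. Most intervals of that family are nested and share reads, and on stretches that belong to 1 interval each 8 of 39 were called lower (camera adjusted p = 0.00874, but unadjusted p = 0.258 with an estimated correlation). The stretch median was -0.20, against -0.27 for whole intervals, and 35 of 39 lay below 0. A stretch had a median standard error of 0.19, so single calls are hard to reach on it.

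Above input in WT were 3 lists. Of 37 long neuronal genes, 15 rose and 0 fell, with 15 adjusted over the list alone, but the list's median of 0.07 turned to -0.08 with offsets that follow abundance. Long intervals can collect more reads, so those offsets may also remove a difference tied to length. All 2225 genes over 100 kb had a WT median of 0.10, with 44.9% called above input and 14.6% below. The list's median was no higher than theirs, so its rise was not set apart from that of long genes in general. Camera gave an adjusted p of 7.45e-06, and the adjusted p = 0.536 with an estimated correlation. After Auts2 came Park2 (0.29 ± 0.03, overlapping), Sorcs3 (0.28 ± 0.04) and the glutamate receptor gene Grid2 (0.24 ± 0.03), whose adjusted p was 0.186 with abundance offsets and a replicate block. Of 36 cadherin and contactin genes, which encode cell adhesion proteins, 17 rose and 2 fell, or 20 and 2 adjusted over the list alone (camera adjusted p = 1.54e-05, adjusted p = 0.199 with an estimated correlation). Cdh4 (0.36 ± 0.04), Cdh6 (0.32 ± 0.04) and Cdh18 (0.28 ± 0.04) rose, as did Cdh13 (0.21 ± 0.04), whose adjusted p was 0.257 with abundance offsets and a replicate block. Of 13 excitatory neuron markers, 7 rose and 2 fell, or 9 and 2 adjusted over the list alone (camera adjusted p = 0.00953, adjusted p = 0.345 with an estimated correlation). Among the risers were the transcription factor genes Foxp2 (0.37 ± 0.04), Rorb (0.31 ± 0.05) and Cux1 (0.26 ± 0.04), and the kinase gene Camk2a fell (-0.33 ± 0.07).

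**Figure D1:**
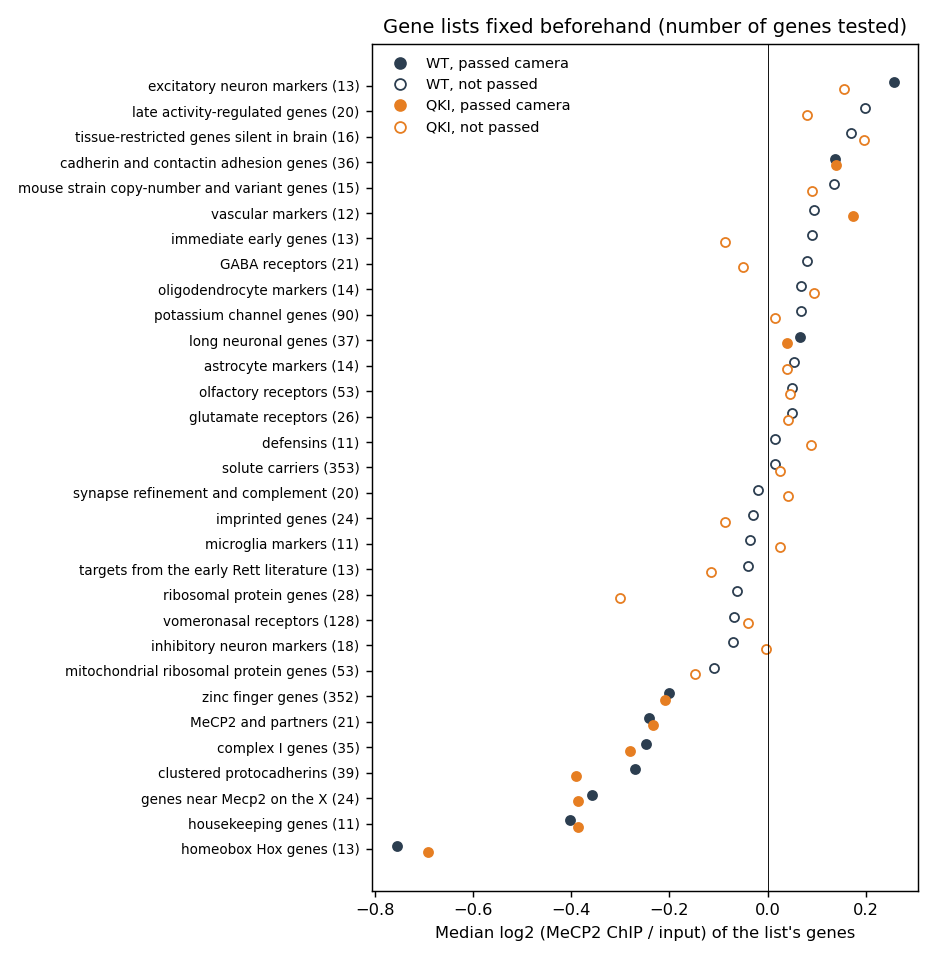
Median log2 MeCP2 ChIP over input of the genes in each fixed list, WT (dark) and QKI (orange), filled where camera with the preset correlation passed. Hox genes lay lowest, at -0.75 in WT and -0.69 in QKI. The WT median of long neuronal genes, 0.07, turned to -0.08 with offsets that follow abundance, which may also remove a difference tied to length. All genes over 100 kb had a WT median of 0.10.

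The same comparison in QKI asked where MeCP2 lay relative to the QKI inputs. Dhrsx (1.21 ± 0.15), Bmi1 (1.13 ± 0.14) and Fgf5 (0.94 ± 0.09; mm10, chromosome 5, start 98257184, end 98277033) rose most of the genes that the rule took. Next were the centrosome gene Nedd1 (0.82 ± 0.06), Wnt16 (0.81 ± 0.12), Dazl (0.74 ± 0.08), Csn1s2a (0.71 ± 0.12), the GABA receptor gene Gabrp (0.71 ± 0.09), Gm5907 (0.70 ± 0.11) and the vitamin D hydroxylase gene Cyp24a1 (0.70 ± 0.13). The largest falls that the rule took were on Ttyh1 (-1.06 ± 0.12, overlapping), the phosphatase gene Dusp8 (-0.98 ± 0.13), Pcdhgc5 (-0.95 ± 0.10) and Pcdhgc4 (-0.95 ± 0.09). The microtubule protein gene Map1a (-0.90 ± 0.10, overlapping), the histone methyltransferase gene Dot1l (-0.87 ± 0.07), Pitx2 (-0.87 ± 0.13), Strn4 (-0.85 ± 0.09), Rnf44 (-0.84 ± 0.11) and the transcription factor gene Mef2d (-0.83 ± 0.08, overlapping) followed. Mecp2 lay at -0.56 ± 0.06 (adjusted p = 4.67e-07), Auts2 at 0.29 ± 0.04 (adjusted p = 1.03e-06) and Bdnf at 0.22 ± 0.06 (adjusted p = 0.00293). Nrxn1 lay at -0.13 ± 0.05 (adjusted p = 0.0265), a call that ended, with adjusted p-values up to 0.148, when either of 4 libraries was left out (QKI inputs 1 and 2, QKI ChIP 2 and 3). It also ended with DESeq2 size factors (0.0537), the DESeq2 test (0.0647) and only the libraries of the comparison (0.104). With density offsets Nrxn1 lay at 0.07. Npas4 (-0.31 ± 0.27) and Gapdh (-0.58 ± 0.27) did not pass.

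By the same test, 7430 genes (41.5%) passed in QKI, 3395 above input and 4035 below, of which 770 differed by more than 1.5-fold and 76 by more than 2-fold. Library-size scaling gave 2575 above and 4778 below, and density offsets gave 3729 above and 3139 below (3158 and 2512 in WT). The lists below input were the same 7 as in WT. Of MeCP2 and its partners, 12 fell and 1 rose of 21, also adjusted over the list alone (camera adjusted p = 0.00016, adjusted p = 0.336 with an estimated correlation), with Dnmt3a at -0.53 ± 0.05, Ncor2 at -0.47 ± 0.05 and Cdkl5 at -0.43 ± 0.06 (overlapping). Of 13 Hox genes 9 fell, or 10 adjusted over the list alone (0.00078, adjusted p = 0.181 with an estimated correlation), among them Hoxc9 (-1.26 ± 0.24) and Hoxb3 (-0.62 ± 0.12). Of zinc finger genes 120 fell and 18 rose, or 117 and 18 adjusted over the list alone (0.00016, adjusted p = 0.181 with an estimated correlation), with Zfp592 at -0.40 ± 0.06. Of genes near Mecp2 10 fell, or 11 adjusted over the list alone (0.00078, adjusted p = 0.181 with an estimated correlation), with Hcfc1 at -0.82 ± 0.13. Of complex I genes 13 fell and 1 rose, also adjusted over the list alone (0.00752, adjusted p = 0.353 with an estimated correlation), with Ndufa10 at -0.43 ± 0.08 and Ndufs1 at -0.34 ± 0.07 (overlapping). Of 39 clustered protocadherin genes 36 fell, also adjusted over the list alone (2.52e-19, adjusted p = 0.181 with an estimated correlation), with Pcdhgc3 at -0.74 ± 0.09. Of their 39 separate stretches 9 were called lower (camera adjusted p = 0.0237, but unadjusted p = 0.307 with an estimated correlation). The stretch median was -0.28, against -0.39 for whole intervals, and 33 of 39 lay below 0.

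Housekeeping genes passed in QKI with 6 down and 1 up of 11, or 8 and 2 adjusted over the list alone (camera adjusted p = 0.0361, adjusted p = 0.353 with an estimated correlation), with Ywhaz at -0.52 ± 0.08 and Polr2a at -0.33 ± 0.09. With same-numbered QKI libraries as a block, the adjusted p of that list was 0.0579. Above input were long neuronal genes, with 15 up and 3 down of 37, also adjusted over the list alone. Camera gave an adjusted p of 0.00078, and the adjusted p = 0.637 with an estimated correlation. They did not pass with fry (adjusted p = 0.0711). Their median of 0.04 turned to -0.01 under library-size scaling and -0.10 with abundance offsets. All 2225 genes over 100 kb had a higher QKI median of 0.10, with 47.5% called above input and 19.2% below. Cadherin and contactin genes had 20 up and 3 down, or 21 and 3 adjusted over the list alone (0.000122, adjusted p = 0.181 with an estimated correlation), with Cdh1 at 0.43 ± 0.06. Vascular markers had 6 up and 1 down of 12, or 7 and 1 adjusted over the list alone (0.0169, adjusted p = 0.353 with an estimated correlation), among them Abcc9 (0.40 ± 0.06, overlapping) and Acta2 (0.53 ± 0.12). Pecam1 (0.22 ± 0.07) and Vwf (0.18 ± 0.06) also rose but lost their calls when QKI ChIP replicate 2 (adjusted p = 0.143 for Pecam1) or QKI input 1 or ChIP 3 (up to 0.126 for Vwf) was left out, and both calls also ended with library-size scaling and with density offsets. The vascular list itself did not pass without QKI input replicate 1, nor did the long neuronal list without QKI ChIP replicate 1 or the housekeeping list without QKI input 2 or ChIP 3. Vascular markers did not pass in WT, where the adjusted p was 0.178, and excitatory neuron markers did not pass in QKI (0.0648), though they did with the block within genotype (adjusted p = 0.0221, but adjusted p = 0.454 with an estimated correlation). The tests of the difference itself gave 0.0591 for vascular and 0.445 for excitatory markers. With that block the vascular list passed for the difference (adjusted p = 0.00674, but adjusted p = 0.404 with an estimated correlation). Against the WT mean the vascular median was -0.15, -0.07 and 0.01 in QKI ChIP 1 to 3. In QKI inputs 1 to 3 it was -0.19, -0.09 and -0.07, so the difference went with lower input and not with higher ChIP counts.

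The main genotype question was whether MeCP2 over gene bodies, corrected for input, differed in QKI. The profiles of WT and QKI lay close together. Dhrsx and Bmi1 had the largest rises in both under the naming rule, and the log2 changes of the 17915 genes correlated across genes at Pearson r = 0.785 and Spearman rho = 0.805. For genes with a mean count of at least 100, r was 0.901. Genes are not independent replicates, so no p is given for these. The 2 profiles share no library. Of genes above input, 2408 were shared by both genotypes (561 would be shared by independent lists of these sizes), and of genes below input 2580 were (683 in independent lists). None of the genes called in both genotypes went in opposite directions.

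**Figure D2:**
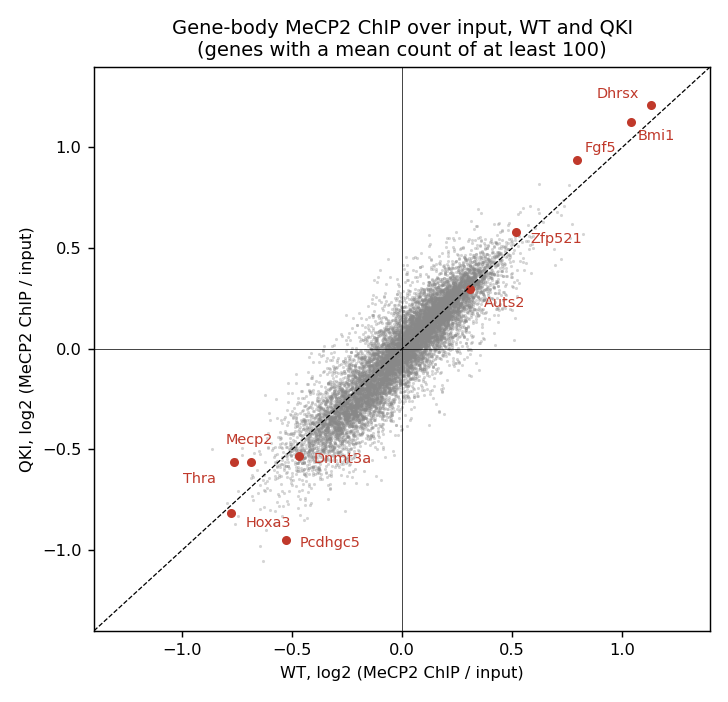
Log2 MeCP2 ChIP over input in WT (horizontal) and QKI (vertical), 1 point for each of 11923 genes with a mean count of at least 100, with equal values on the dashed line. The points follow that line (r = 0.901), from Dhrsx at 1.13 and 1.21 to Pcdhgc5 at -0.53 and -0.95.

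Without a replicate block, no gene passed for the difference between the genotypes' ChIP-over-input ratios. The 0 calls came from edgeR, with a smallest adjusted p of 0.999 and 656 genes under an unadjusted p of 0.05, where chance alone gives 896. Without QKI ChIP replicate 1 that number was 1296, without both QKI replicate 1 libraries 1093, and with same-numbered libraries of a genotype as a block 1233, so it lies on either side of chance. That block, which allows for the correlation of same-numbered QKI libraries, passed 1 gene, the sodium channel gene Scn8a (-0.25 ± 0.05, adjusted p = 0.0208, chromosome 15, start 100873645, end 101045938). The fit without a block takes same-numbered ChIP and input libraries as independent, though QKI ChIP 1 and input 1 correlated at 0.555. It can therefore miss differences, and its 0 calls do not show that there are none. DESeq2 called 0 genes (137 under an unadjusted 0.05) and limma-voom called 0 (659). The genes with the smallest p, none of which passed, were Hapln3 (0.69 ± 0.18), Haus1 (0.60 ± 0.17), Gdf10 (0.75 ± 0.22), Trim36 (0.28 ± 0.08) and the potassium channel gene Kcnj10 (0.33 ± 0.10) on the higher side. On the lower side they were Ppt1 (-0.51 ± 0.12, overlapping), Herpud1 (-0.81 ± 0.21), Krt39 (-0.97 ± 0.27), Apoa2 (-1.49 ± 0.43) and Cct3 (-0.40 ± 0.12). Among the fixed genes, Mecp2 lay at 0.12 ± 0.09, Bdnf at 0.02 ± 0.08, Auts2 at -0.01 ± 0.05, Nrxn1 at -0.07 ± 0.07, Npas4 at -0.13 ± 0.38 and Gapdh at -0.27 ± 0.40. For 96.5% of genes with a mean count of at least 100, the 95% interval of the difference lay within 1.5-fold either way. For all genes that share was 73.6%, and 93.6% lay within 2-fold. The interval of the WT ChIP-over-input change also lay within 1.5-fold for 93.2% of genes with a mean count of at least 100. This bound is therefore wide beside the signal itself and does not show that the genotypes are alike.

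Of the 31 lists, the clustered protocadherins passed for this difference (camera adjusted p = 1.31e-11, lower in QKI), and their adjusted p = 0.673 with an estimated correlation. The number of lists was 1 with all libraries and no block, but 4 with the block within genotype, which added vascular markers (higher) and long neuronal genes and glutamate receptors (lower). With that block and an estimated correlation, none of the 4 passed (adjusted p = 0.404 for vascular markers, glutamate receptors and protocadherins and adjusted p = 0.533 for long neuronal genes). Against the WT mean, the long neuronal median was 0.16, 0.02 and 0.06 in QKI ChIP 1 to 3. In QKI inputs 1 to 3 it was 0.21, 0.08 and 0.05, so that difference went with higher input and not with lower ChIP counts. The number of lists was 7 without QKI ChIP 1, 5 without QKI input 2 or QKI input 3, 3 without WT input 2, and 2 without WT ChIP 1, QKI input 1 or QKI ChIP 2. None of the 39 members passed alone, also adjusted over the list alone. The median member lay at -0.11, with Pcdhgc5 at -0.42 ± 0.14, Pcdhgc4 at -0.41 ± 0.13, Pcdhgc3 at -0.30 ± 0.12 and Pcdhga12 at -0.18 ± 0.08 (chromosome 18, start 37768580, end 37841873). These intervals are nested and share their reads at the 3′ end. On stretches that belong to 1 interval each, the median was -0.00 and the list's adjusted p was 0.723.

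Without input correction, QKI ChIP libraries held fewer counts than WT ChIP libraries on 9 genes, and none was higher. Sfi1, a centrosome gene whose interval overlaps another (mm10, chromosome 11, start 3131850, end 3190463), fell by 1.03 ± 0.12 on the log2 scale (adjusted p = 0.000171). The pseudogene Pisd-ps1, whose interval overlaps that of Sfi1, lay at -0.92 ± 0.16, and Pisd-ps3, on an unplaced scaffold, at -1.01 ± 0.16. Ugt1a1 (-0.65 ± 0.12, overlapping), Zfp600 (-0.63 ± 0.12), Slc22a27 (-0.51 ± 0.09), C130026I21Rik (-0.50 ± 0.09) and Csprs (-0.44 ± 0.06) were the other genes that the naming rule took. The remaining gene was 2410141K09Rik (-0.92 ± 0.18), named after its values were seen. Genes such as Zfp600 and Ugt1a1 are known to have close relatives, which was not tested here and leaves their counts uncertain. DESeq2 called 12 genes and limma-voom called 6. Only Sfi1 passed in each of the 12 fits that left out 1 library. The count was 1 without WT ChIP 1, 2 without WT ChIP 3, 3 without QKI ChIP 1, 5 without WT input 1 or without WT input 3, 16 without QKI input 2, 28 without QKI input 3 and 135 without QKI input 1. Without both QKI replicate 1 libraries it was 58. A fit to the ChIP libraries alone called 80, all but 1 lower.

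The inputs, which hold no immunoprecipitated signal, differed in the same way. In QKI inputs 33 genes were lower than in WT inputs and 1 was higher, Fam53b (0.23 ± 0.05, adjusted p = 0.0428; chromosome 7, start 132712084, end 132810196). Of those that the naming rule took, the lowest were Pisd-ps3 (-0.86 ± 0.16), Sfi1 (-0.83 ± 0.12; adjusted p = 0.00408), the sulfotransferase gene Sult2a1 (-0.78 ± 0.14), the natural killer receptor gene Klra1 (-0.74 ± 0.15) and Gm13212 (-0.70 ± 0.15). Gm13242 (-0.66 ± 0.13), LOC100041034 (-0.64 ± 0.10), Gm15091 (-0.63 ± 0.13), Gm6367 (-0.61 ± 0.11) and C87414 (-0.58 ± 0.12) followed. Outside the rule, 2410141K09Rik lay at -1.07 ± 0.17 and Gm20858, on the Y, at -0.93 ± 0.20, both named after their values were seen. Of the 9 genes lower in QKI ChIP, 7 were also called lower in QKI input, against 0.0166 in independent lists. ChIP and input of a genotype may come from the same tissue, so the 2 lists are not independent. Corrected for input, Sfi1 lay at -0.20 and Csprs at 0.00. DESeq2 called 18 genes and limma-voom called 33. No named call held in each fit that left out 1 library. The count was 0 without WT input 1, 2 without WT input 3, 6 without QKI input 1, 9 without WT input 2, 15 without WT ChIP 3, 17 without WT ChIP 2, 73 without QKI input 2, 153 without QKI input 3 and 210 without QKI ChIP 1. Of the 153 genes 30 were higher in QKI, and of the 210 genes 38, so the near absence of higher genes depends on the libraries used. Without both QKI replicate 1 libraries it was 71, and with the inputs alone 65.

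**Figure D3:**
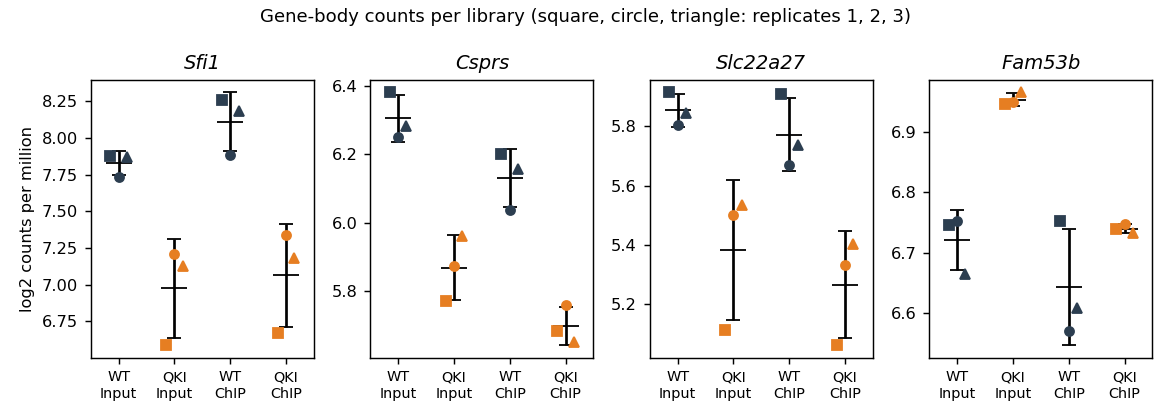
Log2 scaled counts of 4 genes in each of 12 libraries, with replicate 1 as square, 2 as circle and 3 as triangle, and the mean and SD of each group in black. Sfi1, Csprs and Slc22a27 were lower in QKI than in WT in input as well as in ChIP, and Fam53b was higher in QKI input.

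Vomeronasal and olfactory receptor genes passed as lists between genotypes, though not with fry. Of 128 vomeronasal receptor genes, which detect pheromones, 2 passed as lower in QKI input over all genes and 82 did adjusted over the list alone (median -0.46; camera adjusted p = 2.09e-46, adjusted p = 0.229 with an estimated correlation). They were Vmn2r113 (-0.87 ± 0.16) and Vmn2r47 (-0.69 ± 0.14). In ChIP 0 passed over all genes and 56 adjusted over the list alone (median -0.39; camera adjusted p = 3.84e-41, adjusted p = 0.457 with an estimated correlation), with Vmn2r94 at -0.82 ± 0.16, which did not pass. The median of this list against the WT mean was -0.91 in QKI input 1, -0.23 in QKI input 2 and -0.20 in QKI input 3. Olfactory receptor genes had 0 calls of 53 in both assays, also adjusted over the list alone, with medians of -0.21 in ChIP (camera adjusted p = 3.64e-05, adjusted p = 0.539 with an estimated correlation) and -0.22 in input (1.58e-06, adjusted p = 0.341 with an estimated correlation). Olfr872 lay at -0.54 ± 0.17 in ChIP and -0.42 ± 0.15 in input, and did not pass in either. Against the WT mean the olfactory median was -0.37 in QKI input 1 but -0.06 and -0.07 in QKI inputs 2 and 3, where WT input 2 lay at -0.06. In ChIP it was -0.39, -0.13 and 0.01 in QKI replicates 1 to 3. Without QKI ChIP replicate 1 the olfactory list did not pass in ChIP.

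Long neuronal genes lay higher in QKI in both assays, with no gene called over all genes tested. All 2225 genes over 100 kb had medians of 0.05 in input and 0.04 in ChIP, and those under 10 kb of -0.02 and -0.04. The list moved in the direction of that trend but further, as its medians below show. No test against genes of like length was run. Adjusted over the list alone, 23 of 37 passed in input (median 0.11; camera adjusted p = 3.62e-18, adjusted p = 0.229 with an estimated correlation) and 0 in ChIP (median 0.08; 1.91e-17, adjusted p = 0.457 with an estimated correlation). Lrp1b lay at 0.13 ± 0.04 in input and Lsamp at 0.12 ± 0.04 in ChIP, neither past the threshold. Against the WT mean the list's median was 0.21 in QKI input 1, 0.08 in QKI input 2 and 0.05 in QKI input 3. In ChIP it was 0.16, 0.02 and 0.06 in QKI replicates 1 to 3, where WT ChIP 2 lay at 0.04, so that the groups overlapped and replicate 1 stood apart. Other lists passed in 1 or both assays with 0 calls over all genes unless stated, and none with an estimated correlation. In both assays these were glutamate receptors (ChIP 0.0118, adjusted p = 0.539 with an estimated correlation; input 6.9e-06, adjusted p = 0.229 with an estimated correlation), of which 10 rose and 1 fell of 26 in input adjusted over the list alone. Clustered protocadherins passed in ChIP (1.89e-24, adjusted p = 0.454 with an estimated correlation), with 29 lower adjusted over the list alone, and in input (0.022, adjusted p = 0.592 with an estimated correlation). On their separate stretches the median was -0.24 in both assays (camera adjusted p = 6.12e-06 in ChIP and 0.000136 in input), with 0 called and unadjusted p = 0.0786 and 0.125 with an estimated correlation. Zinc finger genes, with Zfp600 called in ChIP, had 2 lower in each assay adjusted over the list alone (ChIP 0.0135, adjusted p = 0.457 with an estimated correlation; input 0.00872, adjusted p = 0.229 with an estimated correlation). Cadherin and contactin genes lay higher in ChIP (0.00737, adjusted p = 0.514 with an estimated correlation) and in input (0.0453, adjusted p = 0.443 with an estimated correlation), where the median of 0.06 turned to -0.01 with abundance offsets.

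In input alone, 6 more lists passed, with no member called over all genes or adjusted over the list alone. Higher in QKI were MeCP2 and partners (median 0.06; 0.0189, adjusted p = 0.494 with an estimated correlation), GABA receptors (0.11; 0.011, adjusted p = 0.346 with an estimated correlation) and potassium channels (0.07; 0.00872, adjusted p = 0.248 with an estimated correlation). Lower were vascular markers (-0.13; 0.000267, adjusted p = 0.229 with an estimated correlation), Hox genes (-0.18; 0.0089, adjusted p = 0.229 with an estimated correlation) and defensins (-0.23; 0.011, adjusted p = 0.229 with an estimated correlation). Examples, none past the threshold alone, were Gabrb2 (0.20 ± 0.06), Kcnq5 (0.17 ± 0.05), Flt1 (-0.20 ± 0.07) and Defb1 (-0.33 ± 0.13). QKI input replicate 1 carried much of this. Without it 5 of the 13 input lists passed, and without both replicate 1 libraries 6 did.

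Gene length was examined because MeCP2 was counted over gene bodies. The median ChIP over input rose from -0.05 in WT and -0.06 in QKI for intervals under 10 kb to 0.10 in both for those over 100 kb. In the longest class 44.9% of 2225 genes passed above input in WT and 14.6% below, and in QKI 47.5% and 19.2%. Across genes, Spearman's rho with length was 0.136 in WT and 0.139 in QKI. Read density in input also varied with the ratio, with rho of -0.24 in WT and -0.27 in QKI. With density held constant the rho with length was 0.179 and 0.189. Density is computed from input counts and interval length, so it shares terms with the ratio and with length. Part of these relations may therefore be built in. The changes from WT to QKI followed density, with rho of 0.388 in input and 0.274 in ChIP. For length these were 0.129 and 0.183. Per ChIP library, rho was 0.117 ± 0.025 in WT and 0.120 ± 0.037 in QKI (SD, n = 3). A 2-sided exact permutation test gave p = 0.9, but its smallest possible p is 0.1, so it could not have passed 0.05.

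**Figure D4:**
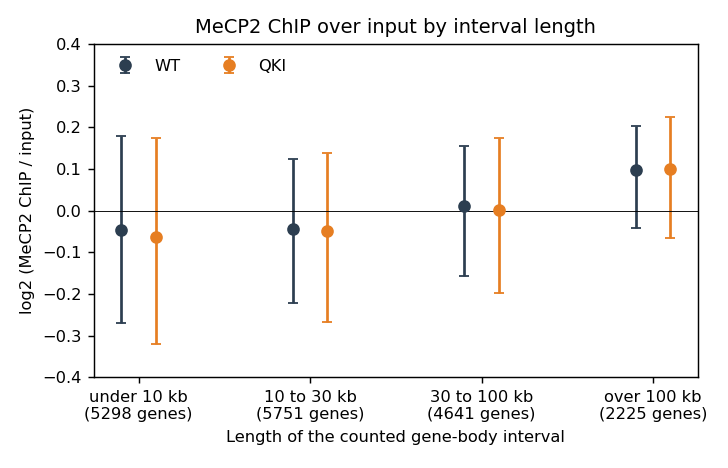
Median log2 MeCP2 ChIP over input by length of the counted interval, with bars from the lower to the upper quartile of genes, for WT and QKI. The medians rise from -0.05 and -0.06 under 10 kb to 0.10 over 100 kb.

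Genes on the X, which carries Mecp2 and is present once in male cells, had slightly less MeCP2 signal relative to input than autosomal genes. The median of 703 X genes was below that of 17177 autosomal genes by a log2 difference of -0.06 in WT and -0.03 in QKI. In WT 6.40% of X genes passed above input and 16.8% below, against 16.96% and 16.92% of autosomal genes. In QKI 10.7% of X genes passed above and 19.9% below, against 19.3% and 22.7% of autosomal genes. Per library the difference was -0.05 ± 0.02 in WT and -0.04 ± 0.02 in QKI (SD, n = 3; 2-sided exact permutation test, p = 0.6). In the inputs, the median read density of X genes lay below that of autosomal genes by a log2 difference of -0.81 ± 0.01 in WT and -0.84 ± 0.03 in QKI (exact p = 0.1, the smallest possible).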

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

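The tests of shared reads, of a single library and of an input difference in this part were chosen only after the list's result had been seen. The clustered protocadherin genes stood out because the test of the genotype difference in ChIP over input passed for them as a list, lower in QKI (camera adjusted p = 1.31e-11, but adjusted p = 0.673 with an estimated correlation). On stretches that belong to 1 interval each, the list's adjusted p was 0.723 and the median was -0.00 (SD 0.27, 20 of 39 below 0), against -0.11 for the whole intervals (SD 0.17). The call of the list therefore fits reads that nested intervals share, although a stretch has a median standard error of 0.28 and small differences would be missed on it. The 3′ stretch at Pcdhgc5 (chromosome 18, start 37822546, end 37841873), counted within each nested Pcdhg interval, lay at -0.42 ± 0.14 (unadjusted p = 0.00477) but did not pass alone, and a biological difference there stays open, as does a single library, since without QKI ChIP 3 it lay at -0.33 ± 0.14. A higher QKI input does not account for the list as a whole, whose median input change was -0.0407 (-0.24 on the stretches), but at the Pcdhgc5 stretch input was higher by 0.12 and ChIP lay at -0.30, so input made up part of that value.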

How the results depend on the processing

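Chosen before the data were examined were the scalings, filters, tests, libraries per fit, replicate blocks, abundance offsets and omissions of 1 library. The density offsets, the fit without both QKI replicate 1 libraries, the block within genotype with an estimated correlation and the separate protocadherin stretches were added after the data had been seen. Restricting the fit to the libraries of a comparison gave no further value for the difference between ratios, which uses all 12. For named genes, 6114 alternative values kept their direction and side of the threshold, 62 passed where the value reported did not, 153 no longer passed and 29 turned in direction. For lists that passed, 555 camera results kept both, 102 no longer passed and 0 turned in camera's direction, though medians of long neuronal and of cadherin and contactin genes turned under other scalings. The WT count of 5992 genes ran from 4168 to 7553 and the QKI count of 7430 from 5608 to 8750. Of the named calls, 58 of 59 in WT, 56 of 59 in QKI, 1 of 8 in ChIP and 0 of 13 in input held with each library left out in turn. Where values moved, the cause was not tested. Genotypes lay closer for genes with more reads, though this filter also changes which genes are compared. The r of WT with QKI was 0.785 for all genes and 0.901 for those with a mean count of at least 100, and the SD of their difference fell from 0.187 to 0.112.

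Counts of genes moved in the genotype comparisons without input correction. The 9 calls in ChIP became 5 with a mean count of at least 100, 80 with only the libraries of the comparison, 16 with density offsets and 58 without both QKI replicate 1 libraries. With 1 library left out they ran from 1 to 135. The 34 calls in input became 18 with the DESeq2 test, 65 with only the libraries of the comparison, 20 with density offsets, 71 without both QKI replicate 1 libraries, and 0 to 210 with 1 library left out. Camera with an estimated correlation passed 0 lists in each of the 5 comparisons, and 0 in the 3 that the block within genotype covers. Fry passed 16 in QKI and 0 in each genotype comparison (14 in WT). Without both QKI replicate 1 libraries 4 lists passed in ChIP and 6 in input. With 1 library left out, 1 to 7 lists passed in the difference between ratios, 3 to 8 in ChIP and 5 to 14 in input.

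Several values of single genes turned in sign. For Auts2 the difference between ratios was 0.0046 with DESeq2 size factors, 8.43e-05 by library size, 0.00405 with a mean count of at least 100, 0.00458 with the DESeq2 test, 0.0155 with density offsets, 0.0242 without both QKI replicate 1 libraries, and -0.0342 to 0.0168 with 1 library left out. Nrxn1 turned to 0.0996 in WT and 0.0708 in QKI with density offsets. The ChIP change of Gapdh was -0.0386 without both QKI replicate 1 libraries and -0.0482 to 0.140 with 1 library left out. For Npas4 the omissions gave -0.40 to 0.0149 in WT, -0.45 to 0.0953 for the difference between ratios, -0.41 to 0.0612 in ChIP and -0.18 to 0.24 in input. For Bdnf the difference between ratios ran from -0.0122 to 0.0641. The rho with length in WT was 0.170 with a mean count of at least 100, and with input count in place of length it was 0.0980 in WT and 0.0932 in QKI. The X difference in QKI ran from -0.0568 to -0.0213, and the SD of QKI minus WT from 0.195 to 0.214, with 1 library left out.

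The replicate block within genotype changed the count of the difference between ratios from 0 to 1, Scn8a (-0.25 ± 0.05, adjusted p = 0.0208), and its lists from 1 to 4. It gave 7553 genes in WT and 8750 in QKI. The WT numbers did not meet the rule for pairing, since same-numbered ChIP and input correlated at 0.105, 0.0975 and 0.0365. Yet each WT ChIP library correlated best with the input of its own number. Single genes chosen after their values were seen also went together by number in WT, such as Ide (inputs 678, 1330 and 650, ChIP 632, 1472 and 672) and Nudcd1 (903, 595 and 644, ChIP 905, 645 and 646). Pairing in WT was therefore not settled. Nrxn1 passed in WT with that block (adjusted p = 0.0291). A replicate block shared by all groups gave 5877, 7336, 0, 8 and 34 calls in the 5 comparisons, without Ugt1a1 in ChIP (adjusted p = 0.0568) and, in input, Gm13212 (0.0524) and the cadherin and contactin list (0.0650). Abundance offsets with the replicate block gave 5653, 7279, 0, 11 and 45, and an Npas4 change in ChIP of 0.00479 (0.00884 without the block). In QKI the housekeeping list ended and the excitatory markers passed. Among the named genes and lists, the block within genotype changed no other call.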

Other observations

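Lists of genes tied to neuronal activity did not pass with camera, but the late activity-regulated genes passed as higher with fry. Fry does not compare a list with other genes, and 14 of 31 lists passed it in WT and 16 in QKI. A pass with fry alone therefore does not show that a list stands out from other genes. The lists below were fixed before the data were seen, and the members named here were chosen after their values were seen. Counts are for WT and then QKI, adjusted over all genes, and adjusted over the list alone only where that differs. Of 13 immediate early genes 3 rose and 1 fell in WT, and 4 rose and 2 fell in QKI (camera adjusted p = 0.506 and 0.929). The nuclear receptor gene Nr4a3 rose (0.34 ± 0.07 and 0.26 ± 0.06), as did Egr3 (0.83 ± 0.19 and 0.57 ± 0.19; mean count 36.8), and the GTPase gene Rheb fell (-0.34 ± 0.07 and -0.41 ± 0.07). Homer1, a gene of the postsynaptic scaffold, fell in QKI (-0.27 ± 0.05) and lay at -0.09 ± 0.05 in WT. Of 20 late activity-regulated genes 6 rose (8 over the list alone) and 3 fell, against 9 and 4 in QKI (0.279 and 0.450; fry adjusted p = 0.00463 and 0.0276). The neuropeptide gene Tac1 (0.75 ± 0.15 and 0.67 ± 0.15) and Baz1a (0.26 ± 0.06 and 0.33 ± 0.06) rose, and Nrn1 fell (-0.48 ± 0.18 and -0.83 ± 0.19). Of 13 targets from the early Rett literature 3 rose and 2 fell, against 2 and 2 (0.951 and 0.740), with Fkbp5 at 0.34 ± 0.05 in both. Of 26 glutamate receptor genes 7 rose and 3 fell, against 7 and 9 (0.430 and 0.941). The kainate receptor gene Grik1 rose (0.28 ± 0.04 and 0.34 ± 0.04) while Grik5 (-0.50 ± 0.08 and -0.62 ± 0.08) and the NMDA receptor gene Grin2b (-0.27 ± 0.06 and -0.39 ± 0.06) fell. Of 21 GABA receptor genes 4 rose and 3 fell, against 5 (6 over the list alone) and 3 (0.430 and 0.893), with Gabbr1 at -0.42 ± 0.09 and -0.77 ± 0.09. Of 20 genes of synapse refinement and complement 1 rose and 2 fell, against 3 and 4 (0.993 and 0.737), with the phagocytic receptor gene Megf10 at 0.28 ± 0.06 and 0.33 ± 0.06.

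No marker list of this paragraph passed with camera in the genotype given, while some lists passed with fry, whose adjusted p is then given. Of 18 inhibitory neuron markers 4 rose and 0 fell in WT, against 3 and 5 in QKI (camera adjusted p = 0.821 and 0.893), with Reln at 0.29 ± 0.04 in both and Adarb2 at 0.23 ± 0.04 and 0.22 ± 0.04. Of 14 astrocyte markers 3 rose and 0 fell, against 5 and 1 (0.549 and 0.520), with the water channel gene Aqp4 at 0.29 ± 0.10 and 0.40 ± 0.10. Of 14 oligodendrocyte markers 3 rose (1 over the list alone) and 0 fell, against 3 and 1 (0 over the list alone; 0.544 and 0.432, fry 0.0327 in QKI), with Pdgfra at 0.35 ± 0.08 and 0.38 ± 0.08. Of 11 microglia markers only Ptprc rose (0.27 ± 0.05 and 0.35 ± 0.05; 0.808 and 0.580). Of 12 vascular markers 2 rose and 1 fell in WT, and of 13 excitatory markers 6 rose and 2 fell in QKI (7 and 3 over the list alone; fry 0.00353). Of 16 tissue-restricted genes 5 rose and 1 fell, against 4 and 1 (0.153 and 0.0576, fry 0.00254 and 0.000714), with the titin gene Ttn at 0.32 ± 0.04 and 0.38 ± 0.04. Of 24 imprinted genes 3 rose and 3 fell, against 3 and 6 (2 and 5 over the list alone; 0.973 and 0.585), with Ube3a at -0.26 ± 0.05 and -0.37 ± 0.05. Of 15 strain copy-number and variant genes 4 rose and 1 fell, against 5 and 2 (3 over the list alone; 0.356 and 0.520), and Sfi1 was the member called between genotypes. Of 53 olfactory receptor genes 3 rose (1 over the list alone), against 2 (0 over the list alone; 0.808 and 0.580). Of 128 vomeronasal receptor genes 1 rose and 4 fell, against 0 and 3, all 0 over the list alone (0.405 and 0.929). Ribosomal protein genes had 2 up and 3 down of 28, against 2 and 7 (0.808 and 0.294, fry 0.0249 in QKI), and mitochondrial ribosomal protein genes 3 and 5 of 53 (3 and 2 over the list alone), against 4 and 10 (4 and 8; 0.430 and 0.132, fry 0.0332 and 0.000549). Potassium channel genes had 14 and 6 of 90 (13 and 6), against 18 and 12 (16 and 11; 0.204 and 0.520), and solute carrier genes 59 and 39 of 353 (53 and 35), against 78 and 58 (77 and 57; 0.569 and 0.445, fry 0.00189 and 0.000833). Of 11 defensin genes 1 rose in each genotype (0 over the list alone in QKI; 0.808 and 0.737), and of 2 histone genes 1 fell in each.

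Of the tests that follow, those of less MeCP2, of QKI replicate 1, of read density, of copy number and of a wider region were chosen only after the result had been seen. Together, 35 genes were called lower in QKI ChIP or input, on 15 chromosomes with unplaced scaffolds not counted. Their median change was -0.49 in ChIP and -0.55 in input, while the difference between ratios had a median of 0.0579 (bootstrap standard error 0.0254 over genes). The bootstrap took the genes as independent, though all come from the same 12 libraries, so its error does not measure the spread between libraries. Choosing most of these genes by their input calls pushes the median of 0.0579 up, so it does not settle whether less MeCP2 is a cause. Among the 9 genes called in ChIP, the difference ran from -0.39 (Pisd-ps1) to 0.15 (2410141K09Rik). Whether QKI replicate 1 alone made the pattern was not settled. Without both of its libraries the input median stayed at -0.40, but the genes had been chosen in fits that held those libraries. Replicate 1 was the lowest QKI input for 34 of the 35 genes and the lowest QKI ChIP library for 32. A fit without both replicate 1 libraries called 71 genes in input, 67 of them lower. With density offsets the input median was -0.44, but the genes had been chosen in fits without those offsets. A fit with density offsets still called 20 genes in input, 18 of them lower. A smooth trend with read density therefore does not account for all input calls, but how much of the pattern it made was not settled. A difference in strain background between the genotypes, or in copies that align to several places, could leave such a pattern of 0.0579 after input correction but was not tested without a genome sequence, and a biological effect of the genotype was not tested.

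Counts over the insulin-degrading enzyme gene Ide (chromosome 19, start 37268741, end 37331544) differed between libraries of 1 genotype. Log2 scaled counts in input were 6.10, 7.06 and 6.03 in WT and 6.88, 7.14 and 6.65 in QKI replicates 1 to 3, and they followed the ChIP library of the same number (r = 0.980, exact permutation p = 0.00556, adjusted p = 0.0167 over 6 genes tested, and rho = 0.886, p = 0.0333, adjusted p = 0.100). Without the 2 farthest pairs r was 0.930, and Btaf1 nearby did the same (r = 0.988, p = 0.00278, adjusted p = 0.0167, rho = 0.943, p = 0.0167, adjusted p = 0.100, r = 0.968 without 2). That relation fits a copy number that differs between mice. Ide and Btaf1 were in the list of strain copy-number and variant genes fixed beforehand, but this test was chosen after the values were seen. The relation may also come from steps shared by libraries of 1 number, which was not tested. Ide ranked only 77 by input range, and 181 of 637 genes with a range over 0.5 had an r over 0.9. Unlike the genes lowest in QKI replicate 1, Ide was higher in QKI input 1 (6.88) than in WT inputs 1 and 3. A difference over the whole region is excluded, since the inputs of Kif11 and Cpeb3 spanned at most 0.207 on the log2 scale, against 1.12 for Ide. Cpeb3 lies between Btaf1 and Ide, so an unbroken difference does not reach from Btaf1 to Ide. On chromosome 15, the inputs of Nudcd1 (start 44375227, end 44425307) were 6.51, 5.90 and 6.02 in WT and 6.67, 5.93 and 6.61 in QKI.

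Other splits of the libraries into groups were tried with the same test. In WT 1 of 10 splits, the real one, called as many genes (5992, highest other 0) and 2 of 10 passed as many lists (10, highest other 11). In QKI these were 1 of 10 (7430, highest other 1) and 4 of 10 (10, highest other 10). In ChIP they were 1 of 10 for genes (9, highest other 0) and 3 of 10 for lists (7, highest other 8), and in input 1 of 10 (34, highest other 0) and 2 of 10 (13, highest other 14). A set of 10 splits is too small for a share under 0.05. For the difference between ratios, edgeR called 0 genes (656 under an unadjusted 0.05), so that 100 of 100 splits reach that number by construction and say nothing about chance. The highest other count was 360, and 90 of 100 splits passed at least 1 list, the highest other 13. These splits exchanged ChIP and input labels separately, so most of them separated same-numbered libraries. The other splits that kept same-numbered libraries together passed 1, 0 and 0 lists, against 1 for the real groups. Of the 7 splits that exchanged all 3 input labels between genotypes, 2 called 360 and 168 genes and 5 called 0. A count of 360 points to a structure of the samples, here a split that adds the genotype differences of ChIP and input instead of subtracting them. Other splits passed as many lists in all 5 comparisons, so the numbers of lists passing do not set the real groups apart. For the difference between ratios, however, counts above 1 came only from splits that separated same-numbered libraries.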
